A study of Pimephales promelas with 65 samples.

How the data were processed

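Gene expression was measured in the brain of adult male fathead minnows (Pimephales promelas) with a 2-colour spotted oligonucleotide array. Per the labels, aquaria received RDX, a nitramine explosive, at a mean of 0.83 mg/L (SD 0.15) for up to a year, or served as controls, with 8 experimental units per exposure. Per the labels, 5 males per exposure were sampled at 1 day and at 1, 3, 6, 9 and 12 months. Each brain RNA was labelled with Cy3 and hybridised together with a pooled brain reference labelled with A647, and 5 further arrays carried the reference in both channels. The series holds 65 arrays, each with 22176 spots, of which 20942 are distinct probes and 1234 are control spots.

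The deposited scanner files give, for every spot, the median intensity of the spot and of its local background in both channels, without background subtraction. Per the file headers, they also give the percent of saturated pixels of each spot. The deposited series table holds a linear ratio of the 635 nm reference channel over the 532 nm sample channel, which the authors normalised by lowess within each array and kept only for spots with a particular scanner flag. These ratios matched the lowess ratio in the scanner files within 1% at 98.88% or more of the filled spots of every array. The table is thinned differently in different arrays, from 2400 to 16429 kept spots, so the intensities were used for the results and the authors' ratios as an alternative.

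Intensities were background-corrected by normexp with an offset of 50 and normalised by loess within each array, with control spots given no weight, in limma 3.58.1 under R 4.3.3 (packages data.table, version 1.17.8, and jsonlite, version 2.0.0). The values are log2 ratios of sample over reference, so a positive value means more signal in the fish's brain than in the pool. A probe was tested when its Cy3 intensity exceeded its local background by 2 background SDs on at least 50% of the arrays of at least 1 group. This left 1774 probes for 1 day to 6 months and 3850 for 9 and 12 months. Empty spots put through the same filter passed at 4.9% in the first stage, against 8.7% of probes, and at 1.7% in the second, against 18.8% of probes. The number of arrays and their low signal over background limit the precision. A further 440 probes, at spots whose name differs between files, were left out.

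The labels say that the first 4 sampling times and the last 2 were handled as separate investigations, so each stage had its own limma model with a mean per group (40 arrays of 39 replicates, and 20 arrays). Of the control 3-month arrays, 2 carry the replicate number 2 and were averaged. RDX at 3 months has no replicate 2, so 1 of these arrays may be an RDX array with a wrong label. The first had a mean correlation of 0.33 with the other controls and 0.31 with RDX, the second 0.25 and 0.22, which does not settle it. Contrasts were RDX minus control at each time, their average over a stage, the difference of the RDX effect between times, and time among controls. For controls over 1 day to 6 months the test was limma's moderated F test, with direction taken from 6 months minus 1 day. Calls are two-sided with a Benjamini-Hochberg adjusted p under 0.05, and fitted intervals have a confidence level of 95%. Counts at an unadjusted p under 0.05 are also given. With no change at all, 88.7 of 1774 probes and 192.5 of 3850 would be expected there. The contrasts, the filter, the gene lists and the rule for named genes were fixed before the data were examined. The plan also had spots flagged as outliers left out, but the main model left out no spot by its flag. Spots that the scanner software did not find, 702 to 11540 of the 20942 probes on an array, therefore stayed in it.

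Gene names are the deposited best-hit descriptions with an E-value of at most 1e-05. Names were usable for 6407 probes, covering 5099 names, and are similarities to sequences mostly of other fish, not identities checked here. None of the 10926 accessions on the array was in the available gene table, so no genome positions are given. The E-value limit, the way the descriptions were cleaned and the exclusion of spots with differing names were set after the files were opened. The named genes are those past the threshold with the largest rises and falls, 10 each way for the average effects and 4 each way for other contrasts. Where under 4 passed, the 4 genes with the lowest p are also given as values that did not pass, and each list is represented by up to 4 members with the lowest p in its best contrast. A gene with several probes is represented by the brightest. Since genes were chosen on the same values, a count of RDX brains above the control mean describes them and is no separate support.

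Of 25 gene lists, those with at least 5 probes in a stage were tested, 8 in the first stage and 12 in the second, by camera with a preset correlation of 0.01 and by camera with an estimated correlation and by fry as alternatives. They are ribosomal proteins, oxidative phosphorylation, glycolysis, glutamate signalling, calcium signalling, oxidative stress and glutathione, heat shock and unfolded protein response, immune and microglia, and, in the second stage alone, synaptic vesicle release, xenobiotic metabolism, steroid hormone axis, and liver and plasma. Adjusted p values of lists are over the lists tested in that contrast.

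A spot was counted as saturated when over 50% of its pixels were, in either channel. Saturation was examined only after several named probes were seen to be saturated, and leaving saturated probes out is an alternative chosen after seeing the data. No fold is given for a named gene saturated in either channel on at least 50% of the arrays of a group, a rule also set after seeing the data. For a time, probes in print blocks whose brightness did not follow the other slide series were left out of the model, a rule made after the first counts were seen. It was withdrawn because it was not in the plan, and is now an alternative that gives 4 called list tests in place of 3 and the same counts of 1 probe at 6 months and 10 among controls. The other alternatives are no background correction, median centring, between-array scaling of brightness, the authors' ratios, other filters, slide-number series or replicate number as a block, array weights, a single model of all 12 groups, brightness as a covariate, and leaving out arrays. Slide-number series is the leading part of the slide number on each array, with some neighbouring numbers joined by hand and others kept apart, which gave 5 series. Other groupings were not run. The averaged control 3-month replicate 2 joins an array of series D and an array of series B, and was counted in D. All 9- and 12-month arrays belong to 1 series, so it could not be a block there.

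The models were tested on simulated data with independent noise between probes. In each simulation 200 probes changed at once, 50 at each size of change. A change put into an average was equal at all its times. Recovery would be lower where few probes change, since the adjusted threshold is then stricter, and this was not simulated. At a log2 change of 1, 42% of changed probes were recovered at 6 months, 96% for the average over 1 day to 6 months, 66% at 12 months, 84% for the average over 9 and 12 months and 54% for time among controls. At a log2 change of 2 these were 94%, 100%, 100%, 100% and 88%. For the difference of the RDX effect among the times from 1 day to 6 months, 20% were recovered at a log2 change of 1 and 86% at 2. Between 9 and 12 months it was 28% and 80%. The simulation was first to recover over 80% at a log2 change of 2 in every contrast. The difference of the RDX effect between 9 and 12 months reached 80%, and this criterion was then replaced by limits on bias, direction and false calls. When the Cy3 signal of 200 probes was doubled on real arrays, a median log2 change of 0.82 was recovered where 1 was put in, so the log2 changes here are compressed.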

Results

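The 65 arrays form 13 groups. Control and RDX brains at 1 day and at 1, 6, 9 and 12 months have 5 arrays each, RDX at 3 months has 4, control at 3 months has 6 arrays of 5 replicates, and the reference against itself has 5. Signal was low on most arrays. Between 2.3% and 9.0% of probes stood above background in the Cy3 channel on each array from 1 day to 6 months (median 4.5%), between 4.6% and 33.1% at 9 and 12 months (median 12.8%) and between 4.3% and 13.1% on the reference arrays. At 6 months the share was 3.3% ± 0.77 in RDX brains and 5.82% ± 1.94 in controls (SD, n = 5 each).

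**Figure D1:**
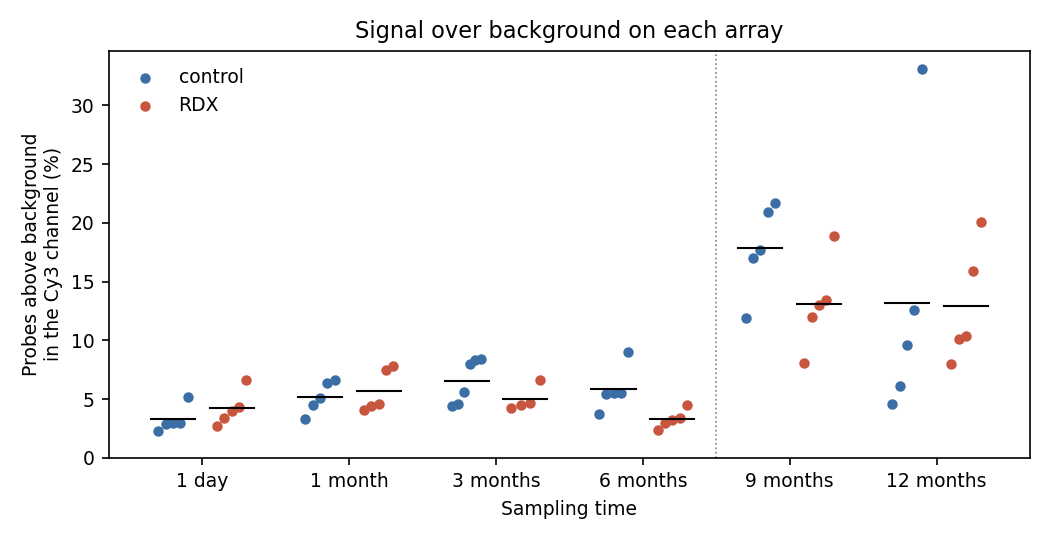
Percent of probes above background in the Cy3 channel on each array, by sampling time, for control (blue) and RDX (red) brains. Points are arrays placed in order of value, bars are group means, and the dotted line parts the stages, with 2.3% to 9.0% before it and 4.6% to 33.1% after it.

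The labels state the purpose as finding genes whose brain expression responds to RDX. The first question is whether RDX changed expression from 1 day to 6 months.

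At 6 months, ubiquitin A-52 residue ribosomal protein fusion product 1 passed the threshold with a log2 ratio higher in RDX brains by 1.45 ± 0.30 (SE, adjusted p = 0.0476), a difference that saturation keeps from being read as a fold. The gene, measured by probe Ppr18349PprS26979571, encodes ubiquitin joined to a protein of the large ribosomal subunit. Its log2 ratio was 0.82 ± 0.46 in RDX brains and -0.63 ± 1.05 in controls (SD, n = 5 each), and 5 of 5 RDX brains lay above the control mean. Its spot was saturated in Cy3 on 4 of the 5 RDX arrays and 2 of the 5 control arrays, and in the reference channel on 5 of 5 RDX and 3 of 5 control arrays. Its RDX mean equals the ratio shared by all probes saturated in both channels (0.82 ± 0.46). It therefore reflects the scanner's ceiling and the normalisation of each array and is not a level of this transcript. It stood above background on 5 of 5 RDX and 3 of 5 control arrays. The 2 control arrays at background, replicates 1 and 4, had -1.80 and -1.75 against -0.09 to 0.33 in the others, and much of the difference rests on them. It was the single probe of 1774 called by limma at 6 months, where 160 had an unadjusted p under 0.05, against 88.7 expected with no change. No probe was called (91 at an unadjusted p under 0.05) once probes saturated on any array of the stage were left out. Leaving out control replicate 1 or 4 or RDX replicate 1, 2, 3 or 4 also gave 0 calls, control replicate 2 gave 2 and RDX replicate 5 gave 7.

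Of the 48 ribosomal protein probes at 6 months, 34 were higher and 14 lower in RDX brains, with a median log2 change of 0.23 against -0.12 for all probes (camera adjusted p = 9.95e-06). The call was lost with an estimated correlation (adjusted p = 0.181). The oxidative phosphorylation list was called higher relative to other probes (adjusted p = 0.00423), although 20 of its 40 probes were higher and 20 lower, with a median of 0.01. Here too the call was lost with an estimated correlation (adjusted p = 0.181). In the immune and microglia list 8 of 9 probes were higher and 1 lower, with a median of 0.68 (adjusted p = 0.00638, and 0.181 with an estimated correlation). No member of these lists passed the test over all probes. Adjusted over the list alone, 1 oxidative phosphorylation probe passed, of cytochrome c oxidase subunit II. It was saturated on 9 of the 10 arrays. Another probe of this gene, saturated on 10, had 0.63, the same value as a subunit I probe saturated on 10, so it is no separate support. The 2 probes of subunit II saturated on 0 arrays had -0.06 and 0.16. Their names differ from those of the saturated 2 only by a trailing r, the meaning of which was not checked. No probe of the other lists passed when adjusted over its list alone at 6 months. With median centring in place of loess, all probes together shifted by a median of -0.45, and the ribosomal median turned to -0.05 and the oxidative phosphorylation median to -0.33. Each stayed above the whole. Within slide series C, the series that holds 3 control and 3 RDX arrays at 6 months, the ribosomal, oxidative phosphorylation and immune medians were 0.40, 0.17 and 1.28, and the other series hold too few arrays to compare.

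Saturation divides these lists, as it divides all probes, where the 280 saturated ones had a median of 0.17 and the 1494 others -0.15. Of the ribosomal probes, 29 were saturated on at least 1 of the 6-month arrays and had a median of 0.36. The other 19 had a median of 0.09. In oxidative phosphorylation the 20 saturated probes had a median of 0.25 and the 20 others -0.03. In the immune list 8 of 9 probes were unsaturated, with a median of 0.63. On each 6-month array the probes saturated in both channels share 1 log2 ratio, which was 0.82 ± 0.46 in RDX brains and 0.19 ± 0.16 in controls (SD, n = 5 each). Such spots have nearly the same intensity in both channels before processing. The ratio is therefore set by the background correction and normalisation of each array, and its difference between groups is not a difference of transcripts. Without probes saturated on any array of the stage the ribosomal and oxidative phosphorylation calls ended (adjusted p = 0.394 for both, medians 0.03 and -0.03). The immune call stayed past the threshold (adjusted p = 0.0173, median 0.58). With no filter on dim probes none of the 3 lists was called (adjusted p = 0.471 for ribosomal proteins and higher for the others, with medians of 0.12, -0.05 for oxidative phosphorylation and 0.03 for the immune list). The lists then held 93, 72 and 93 probes in place of 48, 40 and 9. These medians therefore cover added dim probes and do not show that the same members lost their shift. With array brightness, the share of probes above background, as a covariate all 3 stayed called (adjusted p = 0.000195, 0.025 and 0.032), with medians of 0.15, 0.11 and 0.74 in that order. Leaving out control replicate 1 lowered the ribosomal median to 0.04, with the list still called (adjusted p = 0.0013). The oxidative phosphorylation call also ended with 1 probe per gene (adjusted p = 0.0708, median -0.06) and without RDX replicate 2 (adjusted p = 0.163). Leaving out control replicate 1 or 5 or RDX replicate 3 or 4 ended the immune call (adjusted p = 0.0503, 0.0685, 0.0588 and 0.0547). The immune median, 0.68 with all arrays, was 0.44 without control replicate 1 and 0.50 without control replicate 5. It was 0.98 without control replicate 4.

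**Figure D2:**
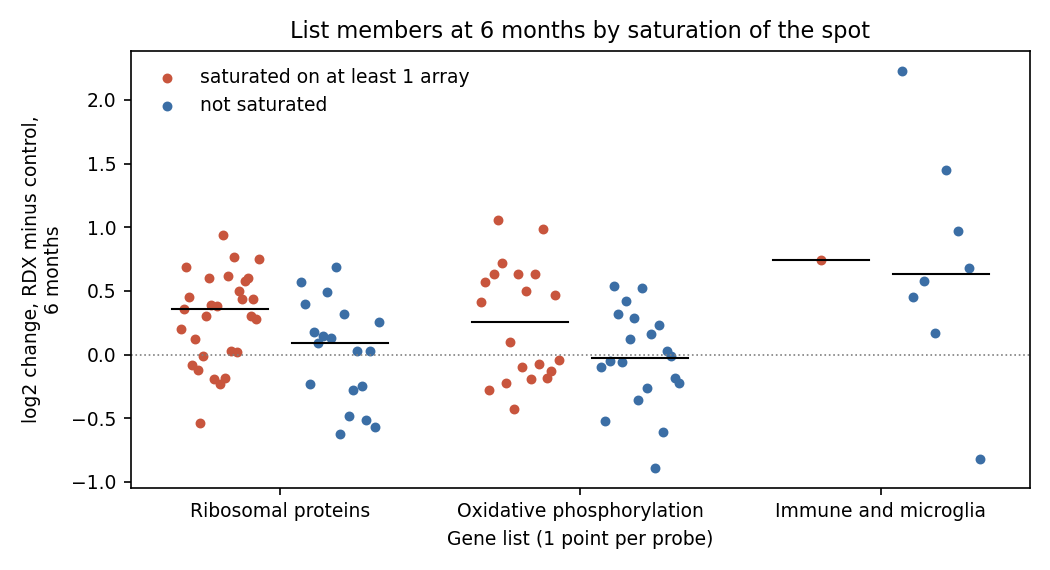
Log2 change of each probe of 3 gene lists at 6 months, RDX minus control, for probes saturated on at least 1 of the 6-month arrays (red) and for the others (blue). Bars are medians, which are 0.36 and 0.09 for ribosomal proteins, 0.25 and -0.03 for oxidative phosphorylation and 0.74 and 0.63 for the immune list.

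Ribosomal proteins L29, L21 and L11 and 40S ribosomal protein S27 did not pass the threshold (adjusted p = 0.346, 0.346, 0.409 and 0.438). L29 was saturated in the reference channel on 3 of 5 arrays in each group and in Cy3 on 1 RDX and 2 control arrays. The others were saturated in the reference channel on 5 of 5 RDX arrays, so no fold is given for any of these probes. Probes of the same genes saturated on 0 arrays had log2 changes of -0.48 and -0.57 for L21, against the direction of the list, and 0.40 for S27, and a second L29 probe, saturated on 1 array, had 0.12. These L21 probes stood above background on 1 of 5 RDX arrays each and on 2 and 3 of 5 control arrays, so their direction is uncertain. No fold is given either for the mitochondrially encoded cytochrome c oxidase subunits I and II and cytochrome b, saturated in Cy3 on 5 of 5 RDX arrays. Nor is a fold given for cytochrome c oxidase subunit III, saturated in Cy3 on 4 of 5 arrays in each group and in the reference channel on 5 of 5 RDX and 4 of 5 control arrays. Its probes saturated on 0 arrays had 0.54 and 0.42, and both pair by name, but for a trailing r, with saturated probes. Cytochrome c oxidase subunit VIa polypeptide 1 (adjusted p = 0.409) is given no fold either, being saturated in the reference channel on 4 RDX and 2 control arrays and in Cy3 on 1 of each. Creatine kinase, brain, which buffers ATP in neurons and glia, was unsaturated and had a log2 change of -0.94 ± 0.28 (SE, adjusted p = 0.346), with 0 of 5 RDX brains above the control mean. Beta-2-microglobulin, the light chain of MHC class I (adjusted p = 0.597), was saturated in Cy3 on 0 arrays, but in the reference channel on 4 RDX and 3 control arrays. Invariant chain-like protein 1, MHC class I UXA2 and the chemokine SCYA103 had 0.68 ± 0.57, 0.97 ± 0.77 and -0.82 ± 0.48 (adjusted p = 0.75, 0.733 and 0.656). They stood above background on at most 2 arrays of either group. The largest change in the list was in a probe of MHC class II antigen, named after its value was seen, with 2.23 ± 0.96 (unadjusted p = 0.0248, adjusted p = 0.447), unsaturated and above background on 2 RDX arrays and 1 control array. The other probe of that name had 1.45 ± 1.34 (adjusted p = 0.789).

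The 5 glutamate signalling probes, which stand for 3 genes and of which 3 are glutamine synthetase 2, were all lower at 6 months, with a median of -0.56 (adjusted p = 0.0909). Glutamine synthetase 1, which turns glutamate into glutamine in glia, had -0.77 ± 0.50 (adjusted p = 0.677), and metabotropic glutamate receptor 8b had -0.39 ± 0.47 (0.834). The brightest glutamine synthetase 2 probe had -0.56 ± 0.41 and the others -1.05 ± 0.42 and -0.03 ± 0.41 (adjusted p = 0.716, 0.409 and 0.983). Of the 8 glycolysis probes 6 were lower, with a median of -0.51 (adjusted p = 0.0763). The heat shock, oxidative stress and calcium lists had medians of -0.33, -0.27 and -0.16 (adjusted p = 0.142, 0.382 and 0.843).

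At 1 day limma called 0 of 1774 probes (60 at an unadjusted p under 0.05). Camera called 0 of 8 lists at 1 day, at 1 month and at 3 months, with the preset and with an estimated correlation, and fry called 0. Ribosomal protein L5 had a log2 change of -0.64 ± 0.21 (SE, adjusted p = 0.999), with 0 of 5 RDX brains above the control mean. The homologue of SMT3, a small ubiquitin-like modifier, measured by probe Ppr12177PprS26889481, had -0.58 ± 0.22. Sin3-associated polypeptide had 0.56 ± 0.22 and human and mouse nitrogen fixation -0.88 ± 0.37 (adjusted p = 0.999 each). These last 3 probes stood above background on at most 1 of 5 arrays in either group. Among oxidative stress genes, of which 8 of 10 probes were lower (list adjusted p = 0.626), phospholipid hydroperoxide glutathione peroxidase A had -0.66 ± 0.34, ferritin heavy polypeptide 1 -0.37 ± 0.30 (but -0.04 without RDX replicate 1), glutathione S-transferase mu -0.43 ± 0.37 and pi-class glutathione S-transferase -0.37 ± 0.34 (adjusted p = 0.999 each).

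At 1 month limma called 0 of 1774 probes (88 at an unadjusted p under 0.05). Myelin basic protein, a main protein of the myelin sheath, had a log2 change of 1.69 ± 0.62 and synaptosome-associated protein 25 b, part of the machinery of vesicle release, 0.92 ± 0.29 (SE, adjusted p = 0.843 each), with 5 of 5 RDX brains above the control mean for each. Within slide series D, with 2 arrays per group, the change of myelin basic protein was -0.37. Quiescin/sulfhydryl oxidase had 1.05 ± 0.38 and vacuolar protein sorting 29 had -0.63 ± 0.24 (adjusted p = 0.843 each). The probes of synaptosome-associated protein 25 b and quiescin/sulfhydryl oxidase stood above background on 1 of 5 arrays in each group. Of the 11 heat shock and unfolded protein response probes 9 were higher, with a median of 0.39 (camera adjusted p = 0.106). In that list heat shock factor binding protein 1 had 0.56 ± 0.26, chaperonin containing TCP1 subunit 4 had 0.87 ± 0.42, DnaJ-like subfamily A member 4 had 0.70 ± 0.79 and heat shock cognate 70 kDa protein 0.34 ± 0.39 (adjusted p = 0.959, 0.992, 0.998 and 0.998), the last with 0.70 in its other probe.

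At 3 months, where the doubled control number leaves 1 array's group label uncertain, limma called 0 of 1774 probes (102 at an unadjusted p under 0.05). Neurogranin, a postsynaptic calmodulin-binding protein, had a log2 change of -2.15 ± 0.75 and metallothionein B, a metal-binding protein, 0.95 ± 0.34 (SE, adjusted p = 0.83 each), with 0 of 4 and 4 of 4 RDX brains above the control mean. Heterogeneous nuclear ribonucleoprotein A/B had -1.26 ± 0.45, with signal above background on 0 of 4 RDX arrays, and sin3-associated polypeptide had -0.62 ± 0.24 (adjusted p = 0.83 each). Of 7 calcium signalling probes 4 were higher and 3 lower (median 0.30, list adjusted p = 0.414). Calmodulin (adjusted p = 0.844) is given no fold, being saturated in Cy3 on 2 of 4 RDX and 2 of 6 control arrays and in the reference channel on 2 and 3, and its other probes had 0.34 and 0. Visinin-like 1 had 1.08 ± 0.81, calcium/calmodulin-dependent protein kinase IV 0.30 ± 0.34 and calbindin 2 like -0.27 ± 0.39 (adjusted p = 0.919, 0.965 and 0.965).

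Averaged over 1 day to 6 months, limma called 0 probes (77 at an unadjusted p under 0.05), with a median half-width of the confidence interval of 0.34 log2, against 0.67 at most single times. The SMT3 homologue had -0.47 ± 0.11 log2 (SE, adjusted p = 0.144), with 1 of 19 RDX brains above the control mean. It stood above background on 6 of 19 RDX and 8 of 21 control arrays. For cytochrome c oxidase subunit III no fold is given, since it was saturated in Cy3 on 14 of 19 RDX and 11 of 21 control arrays and in the reference channel on 17 of each. Its other probes had 0.05, -0.02 and 0.12. Starmaker, named after an otolith protein of zebrafish, had -1.48 ± 0.55 and plasticity-related protein PRG-2 -0.63 ± 0.24 (adjusted p = 0.923 each). Of 8 glycolysis probes 7 were lower, with a median of -0.26 (camera adjusted p = 0.121). Aldolase a had -0.41 ± 0.18, triosephosphate isomerase 1a -0.34 ± 0.19, phosphoglycerate mutase family member 5 precursor -0.27 ± 0.16 and lactate dehydrogenase A4 -0.31 ± 0.25 (adjusted p = 0.923 each). Phosphoglycerate mutase family member 5 entered the list by a match of its name and is not an enzyme of glycolysis. Camera and fry called 0 of 8 lists, and adjusted over the list alone 1 glutamate signalling probe passed. The RDX effect differed between times for 0 probes by limma's moderated F test (102 at an unadjusted p under 0.05).

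The second question is whether RDX changed expression at 9 and 12 months. At 9 months limma called 0 of 3850 probes (153 at an unadjusted p under 0.05) and at 12 months 0 (241 at an unadjusted p under 0.05). Over both times it called 0 (203 at an unadjusted p under 0.05), and the RDX effect differed between them for 0 probes (206 at an unadjusted p under 0.05). Camera called 0 of 12 lists in each RDX contrast, as it did with an estimated correlation, and fry called 0. The median half-width of the confidence interval was 0.55 log2 at each time and 0.39 for the average.

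Glia maturation factor beta, first described as a brain growth factor, had a log2 change of 1.05 ± 0.30 at 9 months (SE, adjusted p = 0.941), with 5 of 5 RDX brains above the control mean. Over both times it had 0.73 ± 0.21 (adjusted p = 0.789), with 10 of 10 above. APG3 autophagy 3-like, an enzyme of autophagosome formation, had 0.62 ± 0.18 and copper chaperone 0.59 ± 0.18 over both times, with 10 of 10 RDX brains above the control mean for each, and Kruppel-like factor 2b had -0.59 ± 0.18, with 0 of 10 (adjusted p = 0.789, 0.792 and 0.792 in that order). At 9 months proteasome subunit beta type 7 had -0.73 ± 0.22, Igfbp2 protein -0.74 ± 0.25 and SH3-domain GRB2-like 2 -1.33 ± 0.49 (adjusted p = 0.941, 0.98 and 0.98), the last with signal above background on 0 of 5 RDX arrays. At 12 months NudC domain containing 2 had 1.09 ± 0.29, v-crk sarcoma virus CT10 oncogene homolog-like 0.92 ± 0.26, sorting nexin 2 0.98 ± 0.28 and cleavage and polyadenylation specific factor 5 0.89 ± 0.26 (adjusted p = 0.584 each). Each stood above background on 3 of 5 RDX and 1 of 5 control arrays.

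The xenobiotic metabolism list at 9 months had 1 probe higher and 4 lower, with a median of -0.69 (camera adjusted p = 0.125). Its named members were cytochrome P450 aromatase, with no fold given, cytochrome P450 family 17 polypeptide 2, like aromatase an enzyme of steroid synthesis, at -1.28 ± 0.50 (SE), carbohydrate sulfotransferase 5 at -0.69 ± 0.38 and cytochrome P450 3A at 0.66 ± 0.48 (adjusted p = 0.98 each). The aromatase probe was saturated in the reference channel on 4 RDX and 3 control arrays and in Cy3 on 0 RDX and 2 control arrays, and its other probe had -0.42. Lists were matched by gene name, and the lower members here are enzymes of steroid synthesis and a carbohydrate sulfotransferase. The list's median therefore does not describe enzymes of xenobiotic metabolism. Both aromatase probes also belong to the steroid hormone axis list, so the falls of these lists are not separate. In the steroid hormone axis list, with 5 of 6 probes lower (median -0.26, adjusted p = 0.422), estrogen receptor alpha had -0.26 ± 0.26, hydroxysteroid (17-beta) dehydrogenase 10 had -0.25 ± 0.25 and 11-beta-hydroxysteroid dehydrogenase-like protein 0.16 ± 0.33 (adjusted p = 0.98, 0.98 and 0.997). In the liver and plasma list, with 4 of 5 probes higher (median 0.18, adjusted p = 0.453), transferrin variant A1 had 0.72 ± 0.38 (0.42 in its other probe), apolipoprotein A-I -0.14 ± 0.28 and apolipoprotein A-I binding protein 0.05 ± 0.24 (adjusted p = 0.98, 0.997 and 0.997). For 14 kDa apolipoprotein (adjusted p = 0.997) no fold is given, since the reference channel was saturated on 4 RDX and 5 of 5 control arrays. Of the 5 synaptic vesicle release probes 2 were higher and 3 lower over both times (median -0.09, adjusted p = 0.603), with synaptotagmin XI at -0.31 ± 0.23, vesicle-associated membrane protein 1 at -0.21 ± 0.20, syntaxin binding protein 1 at 0.16 ± 0.27 and synaptotagmin IV at -0.09 ± 0.35 (adjusted p = 0.989, 0.989, 0.989 and 0.997).

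The third question is how far expression moved with sampling time without RDX, a scale for the exposure effect in which age, season and array handling are joined. Among controls from 1 day to 6 months limma's moderated F test over all these times called 10 of 1774 probes. Of these, 5 had higher and 5 lower means at 6 months than at 1 day, a difference not tested by itself. At an unadjusted p under 0.05 there were 333 probes (18.8%). The adjusted p of each named gene in this comparison is that of the F test. Ba2 globin, a haemoglobin chain of red blood cells, differed most among the named genes. It fell from a log2 ratio of 1.66 ± 0.73 at 1 day to -1.10 ± 1.17 at 1 month, 0.04 ± 1.2 at 3 months and -1.17 ± 1.51 at 6 months (SD, n = 5 each). The change from 1 day to 6 months was -2.83 ± 0.61 (SE, 7.09-fold), with adjusted p = 0.0359 by the F test. It stood above background on 5 of 5 arrays at 1 day and 3 of 5 at 6 months. Quiescin/sulfhydryl oxidase, which forms disulphide bonds, fell from 1.27 ± 0.27 to 0.04 ± 0.34 (SD, n = 5 each, adjusted p = 0.0466), and stood above background on 2 of 5 and 1 of 5 arrays at those times. A kinesin-related motor, named after motors that carry cargo along microtubules, went from 2.11 ± 1.01 to 1.4 ± 0.49 with a low of -0.02 ± 0.53 at 3 months (SD, n = 5 each, adjusted p = 0.0359). Its change from 1 day to 6 months was -0.71 ± 0.44 (SE) but 0.04 with median centring, and it stood above background on 2 of 5 and 3 of 5 arrays at those times.

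Cell division cycle 42, a small GTPase of the cytoskeleton, rose from -1.58 ± 0.59 at 1 day to -0.80 ± 0.43 at 6 months (SD, n = 5 each, adjusted p = 0.0394), and stood above background on 1 of 5 and 4 of 5 arrays at those times. IGHM enhancer 3a-binding transcription factor rose from -1.4 ± 0.48 to -0.48 ± 0.44 (SD, n = 5 each, adjusted p = 0.0466), and stood above background on 1 of 5 arrays at each of those times. The 5 other called probes have no usable gene name. None of the 5 named genes was saturated. The count of 10 was 572 with median centring in place of loess and 40 with slide-number series as a block. It was 3 with array brightness as a covariate and 0 without control 1 day replicate 1.

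**Figure D3:**
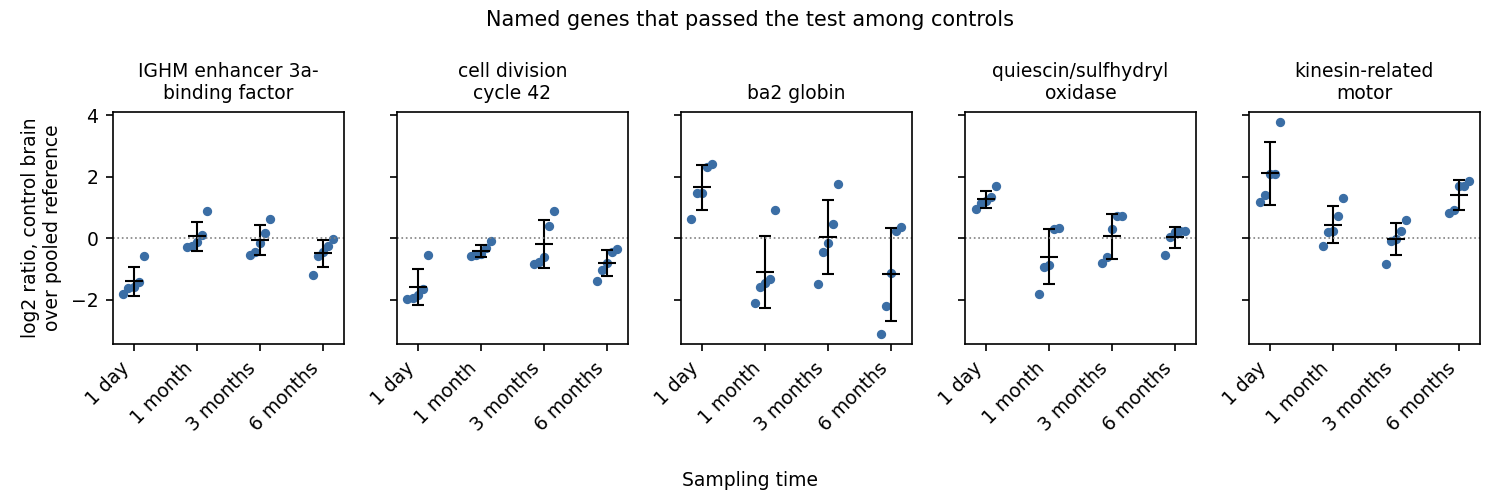
Log2 ratio of control brain over pooled reference at 4 sampling times for the 5 named genes that passed the test among controls. Points are replicates placed in order of value and bars are the mean and SD, and ba2 globin goes from 1.66 at 1 day to -1.17 at 6 months.

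Between 9 and 12 months limma called 0 of 3850 probes among controls (249 at an unadjusted p under 0.05). Protein phosphatase 2 catalytic subunit beta had a log2 change of -1.02 ± 0.26 (SE), vacuolar protein sorting 11 had -1.22 ± 0.33, SLAIN motif family member 1 had 0.89 ± 0.25 and a subunit of the mitochondrial ATP synthase -0.66 ± 0.19 (adjusted p = 0.748 each), with -0.10 in the other probe of the last.

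The reference hybridised against itself was, per the labels, meant to give a false positive rate. Limma called 116 of 1229 probes away from 0 (9.4%), 49 with more Cy3 and 67 with more A647, although both channels held the same RNA. These calls measure a bias between the dyes. They are not a false positive rate of RDX against control, where every brain carried the same dye. The median absolute log2 ratio was 0.21. For false positives between groups, the 5 arrays were divided into 2 against 3, and 1 of the 10 divisions gave any call, of 1 probe. Between 30 and 117 probes had an unadjusted p under 0.05 in a division.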

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

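The tests of brightness and saturation below were chosen after the results they address had been seen and before their own outcomes were known. Those of saturation were chosen after several named probes were seen to be saturated. The model with slide series as a block was fixed before the data were examined. Its use to weigh the results below was chosen after they had been seen and before the outcome of that test was known.

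The RDX effect at 6 months was compared by camera with its mean at 1 day, 1 month and 3 months. Relative to the other probes, 3 gene lists were called higher at 6 months with the preset correlation, and none with an estimated one. The difference holds the same 6-month arrays as the calls above, so it is no separate support for them. Splits of the arrays were not run on it. The median difference was -0.11 log2 for all probes. It was 0.33 for the ribosomal proteins (adjusted p = 4.67e-07, and 0.095 with an estimated correlation), 0.05 for oxidative phosphorylation (0.0161 and 0.305) and 0.77 for the immune and microglia list (0.00425 and 0.2).

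For the ribosomal proteins at 6 months, slide series as grouped here does not account for the shift. With series as a block the median was 0.24 against 0.23 without, a share of 1.05. Chance could not be excluded, since 12 of 100 splits of the 6-month arrays moved the list's mean as far from that of all probes (0.26 for the real split, 0.33 for the highest other). A trend with brightness stays open, as the list's median lay at percentile 97 of random lists of like brightness, whose own median was 0.06. With array brightness as a covariate the list stayed called by camera (adjusted p = 0.000195) at a median of 0.15. Since 36 of the other splits of the 6-month arrays also called the list, that call cannot settle whether array brightness accounts for the shift. Saturated spots stay open as an explanation for the list as a whole. The 19 members saturated on no 6-month array kept 0.37 of its median (0.09, against -0.15 for all unsaturated probes), just above the limit set beforehand for calling saturation the cause. Over a narrower set, the probes saturated on no array of the stage, the camera adjusted p became 0.394. Where a member is saturated in both channels, its value is the ratio shared by all such spots of that array, not a transcript level. All 8 members with an unadjusted p under 0.05, in either direction, were saturated on at least 1 of the 6-month arrays. An effect of RDX on ribosomal transcripts therefore cannot be told apart from the ceiling of the scanner, the normalisation of spots at it and the brightness trend, because the bright members are the saturated ones.

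The count of 3 called lists at 6 months was reached by 17 of 100 splits of the same arrays (highest other 4), so chance could not be excluded, and 70 of the other splits called some list. The same holds for the 1 probe called at 6 months, which 8 of 100 splits matched (highest other 8). It holds too for the 160 probes with an unadjusted p under 0.05 at 6 months, a count that 15 of 100 splits reached. For counts of 0 every split is as large, 100 of 100, which says nothing about an effect. The highest other counts were 121 at 1 day, 4 at 1 month, 4 at 3 months, 1 for the average over 1 day to 6 months and 16 for the difference between those times. They were 4 at 9 months, 28 at 12 months, 24 for the average over both, 8 for the difference between them and 2 for controls between 9 and 12 months, and counts such as 121 and 28 point to a structure of the samples, the nature of which was not tested.

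For controls from 1 day to 6 months chance is unlikely but not excluded. Of 100 splits 1, the real one, gave 10 or more calls (highest other 4), which is the lowest share that 100 splits can show. Slide series as grouped here does not account for the change with time, as 24.2% of probes had an unadjusted p under 0.05 with series as a block against 18.8% without. Saturated spots do not either, with 18.6% among the 1473 probes saturated on no control array. Array brightness stays open for part of it: with the share of probes above background as a covariate 12.4% remained and 3 probes were called, ba2 globin and the kinesin-related motor among them. Age, season and handling on the day, which the design joins to sampling time, were not tested.

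Among 240 tests of a gene in a group, 18 set a brain apart from the others of its group by Dixon's test, where chance alone gives about 1 in 20. The share of probes above background was 33.1% in control 12 months replicate 2, against 4.6% to 12.6% in the others. In control 1 day replicate 4 it was 5.2%, against 2.3% to 3%. The SMT3 homologue had a log2 ratio of -0.93 in RDX 3 months replicate 5, against -0.06 to 0.06. Starmaker had 1.96 in that brain, against -3.55 to -3.14, and 3.35 in control 1 day replicate 5, against -3.48 to -1.67. Plasticity-related protein PRG-2 had 0.13 in control 3 months replicate 5, against 0.80 to 1.06. Cell division cycle 42 had -0.55 in control 1 day replicate 5, against -1.96 to -1.64, and ba2 globin 0.93 in control 1 month replicate 4, against -2.08 to -1.30. Quiescin/sulfhydryl oxidase had -0.55 and aldolase a -1.48 in control 6 months replicate 2, against 0.05 to 0.26 and -0.57 to -0.45. Proteasome subunit beta type 7 had -1.34 in RDX 9 months replicate 4, against -0.59 to -0.41. Cleavage and polyadenylation specific factor 5 had -1.55 in control 12 months replicate 4, against -0.38 to -0.09. Cytochrome c oxidase subunit VIa polypeptide 1 had -3.08 in control 6 months replicate 4, against -0.26 to 0.29. Phosphoglycerate mutase family member 5 precursor had 2.05 in control 1 month replicate 3, against -0.31 to 0.29, and lactate dehydrogenase A4 had 1.54 in control 3 months replicate 4, against -1.84 to -1.28. Cytochrome P450 aromatase had -4.29 in RDX 9 months replicate 5, against -0.81 to 0.32, so the group mean of -1.09 rests largely on that brain. The 11-beta-hydroxysteroid dehydrogenase-like protein had 0.69 in control 9 months replicate 2, against -0.55 to -0.28. Ferritin heavy polypeptide 1 had -2.23 in RDX 1 day replicate 1, against -0.73 to -0.48. Syntaxin binding protein 1 had -0.70 in control 9 months replicate 3, against -0.01 to 0.19, and synaptotagmin IV had -0.84 in control 9 months replicate 5, against 0.78 to 1.09.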

How the results depend on the processing

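Leaving out saturated probes, print blocks, second scans or brightness outliers, the brightness covariate, comparing within a slide series, keeping only spots found on every array, and median centring for the lists were chosen after seeing the data. The counts of the RDX effect at 1 month, at 9 months and averaged over each stage, of its difference among the times from 1 day to 6 months, and of controls between 9 and 12 months stayed at 0 under all their alternatives. Between-array scaling of brightness leaves log ratios as they are, so it tests nothing and is not counted here. For the 6 named genes that passed, 110 of 223 alternative values lost the threshold, 1 reversed and 112 were kept. For the 80 named results that did not pass, 8 of 2338 alternative values gained the threshold and 18 reversed. Of all 86, 21 fell below 50% of their log2 change with a single replicate left out. A block by scan date was not run. Signal over background limits what can be tested, since at most 9.0% of probes stood above it on any array before 9 months. Unless stated, the cause of a change was not tested.

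The count at 6 months (1) was 0 with median centring, the authors' ratios, no filter, the replicate block, the compared groups alone, array weights, the brightness covariate, slide series C alone, brightness outliers left out, and saturated probes left out. It was 2 without background correction and without second scans, 3 with all 12 groups in 1 model, and 15 with probes above background on every array. That filter tested 43 probes, 41 of them saturated on a 6-month array, and all 15 called were among those. Leaving out 1 array gave 0 to 7.

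The count among controls over 1 day to 6 months (10) was 2 without background correction, 572 with median centring, 0 with no filter, and 2 with probes above background on every array. It was 40 and 21 with slide series as a fixed and as a random block, 32 with the replicate block and 16 with array weights. With median centring the median over all probes from 1 day to 6 months was 0.60, against 0.04 with loess. It was 3 with the brightness covariate, 2 without second scans, and 6 without the first and 5 without both of the arrays that share a number. It was 22 with all 12 groups and 6 without brightness outliers. Leaving out 1 replicate gave 0 to 13. It gave 0 without 1 day replicate 1, 1 without 3 months replicate 4, and 2 without 1 month replicate 3 or 5 or 6 months replicate 3. It gave 3 without 1 day replicate 2 or 3 or 6 months replicate 1, 5 without 3 months replicate 2 or 3, and 6 without 1 day replicate 4.

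The count at 1 day (0) was 2 without background correction and 1 without brightness outliers, and 0 to 1 with 1 array left out. At 3 months it was 1 with array weights, and at 12 months 1 with the authors' ratios and 0 to 2 with 1 array left out, 2 without control replicate 3. The difference of the RDX effect between 9 and 12 months was called for 1 probe with the authors' ratios and for 1 with all 12 groups. In the reference against itself the count (116) was 357 with median centring, 37 with no filter and 21 to 117 with 1 array left out. The list count (3) was 6 with median centring, 1 with no filter (none of the 3), 0 with an estimated correlation, 0 with fry, 1 without saturated probes and 2 to 5 with 1 array left out, 5 without RDX 6 months replicate 5.

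With median centring the kinesin-related motor's change reversed to 0.04 and that of apolipoprotein A-I binding protein to -0.03. With the authors' ratios apolipoprotein A-I reversed to 0.08, its binding protein to -0.03 and synaptotagmin IV to 0.18. Within slide series D, with 2 arrays per group at 1 month, myelin basic protein reversed to -0.37, DnaJ-like subfamily A member 4 to -0.70 and heat shock cognate 70 kDa protein to -0.29. With 1 array left out the change of some genes that never passed the test ran to the other side of 0. It ran from -0.27 to 0.13 for synaptotagmin IV, from -0.02 to 0.17 for apolipoprotein A-I binding protein and, with a saturated reference that leaves no fold, from -0.08 to 0.39 for 14 kDa apolipoprotein. It ran from -0.30 to 0.10 for apolipoprotein A-I and from 0 to 0.31 for syntaxin binding protein 1.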

Other observations

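The list of GABA signalling, of interest because RDX is known to bind the GABA-A receptor, has 7 probes on the array, of which 2 passed the filter in each stage, too few to test. The blood list, to which globins belong, had 2 probes from 1 day to 6 months, so whether blood in the tissue changed with sampling time was not tested beyond ba2 globin. The lists for myelin, neurons, muscle and neuropeptides and brain hormones had 3, 2, 2 and 2 probes in the first stage.

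Whether RDX had a shared effect in the separately fitted stages was tested as a hypothesis. Over the 1431 probes tested in both, the average RDX effects of the stages had a Spearman's rho of -0.07, and 25 of 100 relabellings of exposure within time points gave a lower value, with a range of -0.24 to 0.30. The data give no sign of a shared effect. Probes are not independent replicates, so the relabellings and not the number of probes carry this test.

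The brightness of 4 print blocks in each stage did not follow that of the same blocks in other slide series, for 2 of those at 9 and 12 months on all 20 arrays and for the others on some arrays. Cytochrome c oxidase subunit II, plasticity-related protein PRG-2 and apolipoprotein A-I binding protein lie in such blocks, so the identity of their spots on those arrays is uncertain. Brightness on the reference arrays had a median Spearman's rho of 0.05 to 0.08 with the other series, so the 116 probes off 0 there carry no gene names here.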
